A study of Drosophila melanogaster with 20 samples.

How the data were processed

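Gene expression was measured on 20 Affymetrix Drosophila Genome 2.0 arrays, each hybridised with biotin-labelled cRNA from heads of male flies aged 0 to 3 days. Per the labels and the series' design text, each array stands for its own transgenic line, and the control arrays of an experiment come from separately derived control lines, so the spread between arrays of a group includes differences between lines. Groups, line numbers and transgene copies were taken from the sample titles.

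The deposited values are 1 linear signal intensity per probe set and array. Per the submitters' processing notes they were made with GCOS 1.2, Affymetrix's array software. The settings are not given in the sources used here. The deposited intensity values carry a global scaling of each array that can be read from the values: the mean of the central 96% of probe sets, with 2% trimmed at each end, is 100 on 8 of the 11 arrays of the elav c155 experiment and 500 on the other 12 arrays. The arrays at 100 are control 1, every 2x CAG line, every 2x CUG line and 2x CAA line 1. The plan made before the data were examined was to keep the values as deposited, and was changed once these different targets were seen: signals of arrays at target 100 were multiplied by 5, so that all arrays share the target of 500. Results from the values as deposited are given among the alternatives. A linear rescaling does not undo other differences in hybridisation or scanning between arrays at different targets.

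Of 18952 probe sets, 183 control probe sets were left out and 18769 were kept. Signals were transformed to log2(signal + 5.3), the offset being the 10th percentile of the rescaled signals, so a fold change understates the change of dim probe sets. The 11261 probe sets with a mean log2 value of at least 5.37, the 40th percentile, were tested. The platform's annotation table gave 13647 of the kept probe sets 1 gene symbol, 402 several and 4720 none. The tested ones with 1 symbol number 9643 and cover 8609 genes. Probe sets with several or no symbols were counted and not named. No probe set carried the symbol w or sgg, and these genes were not analysed here. The number of arrays limits the precision. Rescaled median signals ran from 78.0 to 99.6 and the 10th percentiles from 3.89 to 7.84.

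The principal components of the 11 elav c155 arrays separated the arrays by something other than genotype. From the scaling target and the log2 signal of the spiked-in control probe set AFFX-LysX-3 (above or below 8), and after those components had been seen, these arrays were put into 3 array sets. Set A holds control 1, 2x CAG line 2, 2x CUG line 1 and 2x CAA line 1. Set B holds 2x CAG lines 1 and 3 and 2x CUG lines 2 and 3, and set C, at target 500, holds control 2 and 2x CAA lines 2 and 3. Array set took 41% of the variance among these arrays, against 20% for exchangeable arrays, and genotype took 30.2%, against 30%. The labels give no batch, slide or scan. A fit with the array set as a fixed block was added after the data were seen, and its values are printed beside results that it changes. Set B holds no control or CAA array, and set C no CAG or CUG array. With the block, CAG and CUG in elav c155 are therefore linked to control and CAA only through set A, with 1 array per group. Block values of these contrasts rest on those few arrays and are not corrected estimates.

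Differences were tested with limma 3.58.1 in R 4.3.3: lmFit with 1 mean for each of the 9 groups, contrasts, eBayes with an intensity trend, two-sided, with Benjamini-Hochberg adjustment within each comparison and an adjusted p under 0.05. Comparisons over both experiments average the effects of the elav c155 and elavII experiments with equal weight. The 4x AUUCU group is 1 array, which is assumed to vary like the other groups. Fits of each experiment alone were planned as an alternative. All adjusted p-values in the text come from limma unless another test is named. The median residual SD on the log2 scale was 0.23 over all arrays, 0.18 with the array set as a block, 0.16 in the elavII arrays alone and 0.24 in the elav c155 arrays alone.

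Before the data were examined, 30 gene lists and the rule for naming genes were fixed. Genes without a probe set of their own symbol, or under the filter, dropped out of the lists. Of the genes written, 21 of 32 were tested for Akt/Gsk3 signalling, 9 of 26 for Wnt signalling and 22 of 53 for humoral immunity. The list called splicing or splicing factors was written to hold repeat-RNA and alternative-splicing factors. It includes other RNA-binding genes such as pum, orb and Fmr1, so its shifts do not stand for splicing factors alone. A list's shift was tested on 1 probe set per gene with camera at a preset correlation of 0.01, adjusted over the 30 lists within a comparison, and again with the correlation estimated from the residuals. For each list, members past 0.05 were also counted after adjustment over the list alone. Named genes have 1 symbol, pass the threshold and, outside the interactions, lie beyond every control array of their experiment on every repeat array: up to 10 with the largest rise and 10 with the largest fall for a repeat against control over both experiments, 5 and 5 against CAA, and 3 and 3 within 1 experiment and for interactions, with Akt and elav always named. From lists, up to 4 members past the threshold or the 2 with the smallest p were the rule. Further members, and up to 10 genes each way from fits added later, were chosen after their values were seen.

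On simulated data with 200 changed probe sets among 11261, the procedure recovered 62% of changes of log2 1 and 86% of log2 2 for 4x CUG versus control, 43% and 83% for 4x AUUCU, 61% and 96% for 2x CUG, 81% and 94% for CUG over both experiments, and 78% and 99% for CUG versus CAA. For the CUG interaction between the experiments it recovered 37% and 80%. In 20 simulated lists of 30 genes shifted by 0.5, camera called 20 at an unadjusted p under 0.05, and it called 1 unshifted list. The simulated genes varied independently. These runs therefore do not show how often camera calls an unshifted list of correlated genes.

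The alternatives tried were quantile normalization, median centring of each array, no offset, no filter, no intensity trend, the line or replicate number as a block, an additive model, a separate fit per experiment, the methods' t-test, and leaving out each array in turn. Added after seeing the data were blocks for array set and scaling target, the values as deposited, the methods' t-test on rescaled linear values, and the elavII arrays alone with quantile normalization or without each array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.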

Results

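Transcript levels were compared between heads of young adult males that express an expanded, untranslated repeat RNA in neurons and heads of control males carrying the GAL4 driver alone. The repeats were CAG, CUG, CAA and AUUCU. Expansions of CAG, CUG and AUUCU underlie human neurological disease, and CAA is a sequence that forms no hairpin. In the experiment with elav c155, an enhancer trap in the neuronal gene elav, 2 control arrays were set against 3 lines each of CAG, CUG and CAA with 2 transgene copies (2x). In the experiment with the elavII driver, 2 control arrays were set against 2 lines each of CAG, CUG and CAA and 1 line of AUUCU, all with 4 copies (4x). Across probe sets, pairs of arrays correlated at 0.94 to 0.973, and no pair was identical. Among the elav c155 arrays the actin 3'/5' signal ratio was 2.38 to 2.50 on the log2 scale in array set C and 1.26 to 1.60 in sets A and B. That of Gapdh went the other way, 3.65 to 4.01 in set C and 4.04 to 4.41 in sets A and B. In the elavII arrays the actin ratio was 3.08 and 3.48 in the controls, 2.82 and 2.99 in 4x CUG, 2.86 in 4x AUUCU, 2.81 and 3.27 in 4x CAG and 2.77 and 3.40 in 4x CAA, so that both CUG arrays and the AUUCU array lie below both controls. The Gapdh ratio did not share this direction. It was 4.27 and 4.46 in the controls, 4.48 and 4.55 in 4x CUG and 4.08 in 4x AUUCU. The study's title names the Akt/Gsk3-beta pathway as its subject.

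A Toll response gene and a glial gene were among those that rose in the 4x CUG lines (n = 2) against the elavII control (n = 2). BomS4, a secreted peptide of the Toll immune response, rose 5.06-fold (log2 change 2.34, SE 0.45, adjusted p = 0.0432), and alrm, a leucine-rich repeat gene of astrocyte-like glia, rose 3.80-fold (log2 change 1.93, SE 0.36, adjusted p = 0.0397). CG4593 rose by 1.93 (SE 0.37, adjusted p = 0.0432). X11Lbeta, a PTB-domain adaptor, changed by -2.64 (SE 0.47, adjusted p = 0.0342), Evi5, a Rab GTPase-activating protein, by -1.79 (SE 0.27, adjusted p = 0.0189) and Rnf11, a RING-domain protein, by -1.37 (SE 0.26, adjusted p = 0.0432). Each of these 6 genes lay beyond both controls on both CUG arrays. In all, 26 of 11261 probe sets passed limma's threshold, 14 higher and 12 lower, and 1205 had an unadjusted p under 0.05. With median centring the count was 69, with 62 higher and 7 lower.

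Fitted to the elavII arrays alone, the same comparison called 432 probe sets, 316 higher and 116 lower, which included all 26. Gat, the GABA transporter of astrocytes, rose by 2.51 (SE 0.62 and adjusted p = 0.119 over all arrays, adjusted p = 0.00115 in the elavII arrays alone). The antimicrobial peptide genes DptB and Mtk rose by 2.21 and 2.04 (adjusted p = 0.0165 and 0.0101 in the elavII arrays alone), and the stress-induced peptide gene TotC by 2.52 (adjusted p = 0.024). CG7509 rose by 2.66, Jhbp15 by 2.13, CG5966 by 1.85, and the detoxification genes Ugt37A3 and Cyp6a23 by 1.87 and 1.83 in this fit. The largest falls there were those of the G protein-coupled receptor gene mthl8 (-4.15), X11Lbeta, CG8508 (-2.05), CG4229 (-1.79), Evi5, Rnf11 and CG33798 (-1.26). SPR, the sex peptide receptor, changed by -1.26, the ubiquitin ligase gene gol by -1.18, the potassium channel gene Sh by -1.05, and the phosphatase gene Ssu72 by -1.02. Of the genes given here only for the elavII arrays alone, CG5966, SPR, Sh and Ssu72 also passed over all arrays (adjusted p = 0.00864, 0.0342, 0.0397 and 0.0433).

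**Figure D1:**
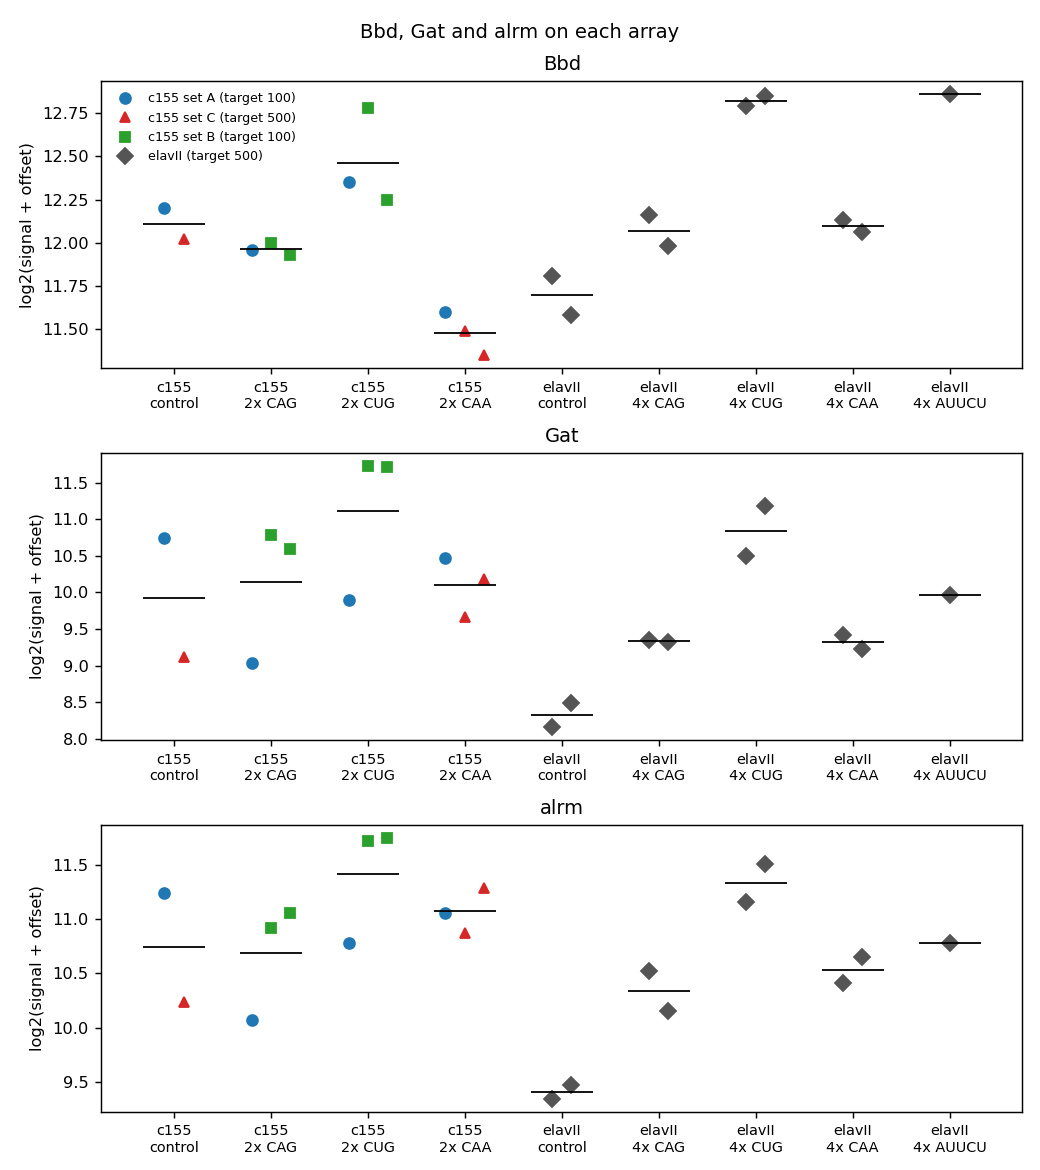
Log2(signal + 5.3) of Bbd, Gat and alrm on each of the 20 arrays by group, with points marked by array set and a bar at each group mean. Both 4x CUG arrays (alrm 11.16 and 11.51, Gat 10.50 and 11.18) lie above both elavII controls (alrm 9.35 and 9.47, Gat 8.16 and 8.49), while the elav c155 arrays spread from 10.07 to 11.75 for alrm.

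The count for 4x CUG rests on few arrays. It was 0 without elavII control 2, 4 without elavII control 1, 1 without either 4x CUG line and 13 without either 4x CAA line. Without elav c155 arrays it was 63 without either control, 3 without 2x CAG line 1 or 3, 72 without 2x CUG line 1, 17 without 2x CUG line 3, 50 without 2x CAA line 1 and 15 without 2x CAA line 3. In the elavII arrays alone it was 71 without control 1, 17 without control 2 and 286 without CUG line 2.

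Of the 30 gene lists, 12 shifted as a whole in 4x CUG by camera, and 11 of them lost the call with an estimated correlation, from which the second adjusted p of each list comes. Humoral immunity rose (22 members, 19 up and 3 down, median log2 change 0.67, adjusted p = 1.04e-08, and adjusted p = 0.0204 with an estimated correlation). 0 members passed over all genes, and 12 rose and 1 fell adjusted over the list alone, among them TotC, Mtk, pirk (1.50) and PGRP-SB1 (1.39), while Def fell (-0.79). Detoxification rose (75 members, median 0.32, adjusted p = 7.3e-06, and adjusted p = 0.247 with an estimated correlation), with 12 up and 2 down adjusted over the list alone, including the cytochrome genes Cyp4e3 (1.76) and Cyp9b1 (1.07) up and Cyp6a9 (-1.64) down. Fat body genes rose (22 members, median 0.34, adjusted p = 0.0011 and 0.291) with none past the threshold adjusted over the list alone, and 10 in the elavII arrays alone, such as the lipid droplet gene Lsd-1 (0.92), fit (1.48) and Tsf1 (0.78). Glia genes (20 members, median 0.087, adjusted p = 0.00678 and 0.247; alrm and wun2 adjusted over the list alone), odorant binding genes (33 members, median 0.21, adjusted p = 0.00722 and 0.315; Jhedup, 0.90) and endoplasmic reticulum stress genes (16 members, median 0.11, adjusted p = 0.0113 and 0.247; none alone) also rose.

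Muscle genes fell in 4x CUG, all 23 members lying below 0 (median -0.37, adjusted p = 5.85e-08, and adjusted p = 0.247 with an estimated correlation). 4 of them passed adjusted over the list alone: troponin C TpnC41C (-0.92), the titin-like sls (-0.81) and bt (-0.59), and Strn-Mlck (-0.48). The other lists that fell were synaptic transmission (45 members, median -0.17, adjusted p = 0.00021 and 0.291), phototransduction (31, -0.24, adjusted p = 0.000141 and 0.247), splicing factors (34, -0.18, adjusted p = 0.0011 and 0.247), circadian clock (14, -0.31, adjusted p = 0.0102 and 0.247) and Wnt signalling (9, -0.22, adjusted p = 0.0354 and 0.291), the second again with an estimated correlation, with 0 members passing adjusted over the list alone. In the elavII arrays alone the immune list had adjusted p = 0.274 with an estimated correlation. Median centring moved the median of all genes in 4x CUG by 0.15 and ended the call of the Wnt list (adjusted p = 0.0755). Leaving out elavII control 1 ended those of Wnt, clock and odorant binding (adjusted p = 0.117, 0.0638 and 0.237), control 2 that of endoplasmic reticulum stress (0.147), and CUG line 1 those of Wnt, endoplasmic reticulum stress, clock and glia (adjusted p = 0.161, 0.0565, 0.0687 and 0.0687).

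The remaining 18 lists passed no threshold in 4x CUG. Their median log2 changes and adjusted p were -0.15 and 0.0787 for Akt/Gsk3 signalling, -0.10 and 0.58 for small-RNA machinery, 0.11 and 0.727 for heat shock, -0.15 and 0.145 for neuropeptides, -0.16 and 0.132 for eye pigment, 0.073 and 0.58 for cuticle, -0.30 and 0.58 for gut digestion, -0.13 and 0.682 for testis, 0.44 and 0.145 for sex markers and -0.047 and 0.76 for apoptosis and JNK. For autophagy the median was -0.074 and the mean 0.0023 (adjusted p = 0.76), for glycolysis 0.052 (0.162), for ecdysone response -0.20 (0.162), for axonal transport -0.075 (0.58), for nuclear export -0.053 (0.364), for ribosomal proteins -0.049 (0.58), for oxidative phosphorylation -0.040 (0.162) and for the proteasome -0.0099 (0.957). The median of the Akt/Gsk3 list changes sign with median centring, and without 4x CUG line 2 the list passed (median -0.23, adjusted p = 0.00979).

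**Figure D2:**
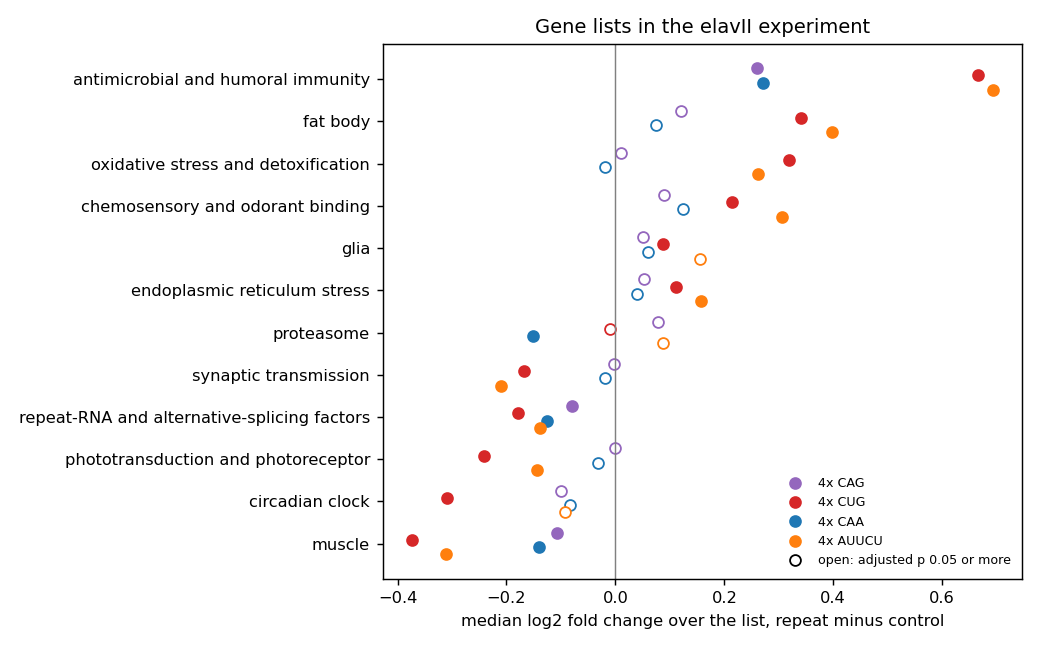
Median log2 fold change of 12 gene lists in 4x CAG, 4x CUG, 4x CAA and 4x AUUCU against the elavII control; filled points passed camera's adjusted p of 0.05 and open points did not. Immunity lies at 0.67 in 4x CUG and 0.69 in 4x AUUCU, and muscle at -0.37 and -0.31; with median centring the splicing, phototransduction and Wnt medians of 4x AUUCU lie above 0.

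The 4x AUUCU line is 1 array, so its tests rest on the spread of the other groups and describe this array rather than AUUCU lines. Bbd, a secreted protein of the Toll response, rose 2.23-fold (log2 change 1.16, SE 0.19, adjusted p = 0.0444), CG7386 was 4.01-fold lower (SE 0.31 on the log2 scale, adjusted p = 0.0444) and Rtel1, a helicase gene, changed by -1.41 (SE 0.21, adjusted p = 0.0442). These 3 were the calls of limma, 1 up and 2 down, with 626 probe sets at an unadjusted p under 0.05. Median centring gave 4, with 3 up and 1 down, and quantile normalization 2, with 1 up and 1 down. In the elavII arrays alone 21 passed, 13 up and 8 down. The rises there included Gat (1.63), CG5966 (1.41), alrm (1.38), CG9394 (1.30) and the Bomanin gene BomT2 (1.29), and the falls the cell adhesion gene Dscam2 (-2.65), SPR (-1.52), the RNA-binding gene sm (-0.91) and pdgy (-0.82). The count over all arrays was 0 without either elavII control, without either 4x CUG line or without 2x CAG line 1, 1 without 2x CAG line 2, 2x CUG line 1 or 4x CAG line 2, 5 without 2x CAA line 2 or 3, 6 without either elav c155 control and 8 without 2x CAA line 1, and no array of the group itself could be left out.

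Immune genes were higher in the AUUCU array for 21 of 22 members (median 0.69, adjusted p = 2.31e-11, and adjusted p = 0.00716 with an estimated correlation). 0 passed adjusted over the list alone, and in the elavII arrays alone 15 rose and 1 fell (adjusted p = 0.155 for the list with an estimated correlation). The other lists lost the call with an estimated correlation, from which their second adjusted p comes. Fat body genes rose (19 of 22 up, median 0.40, adjusted p = 5.63e-06 and 0.31), 2 of them adjusted over the list alone: Cyp4g1 (2.00), a cytochrome of oenocyte hydrocarbon synthesis, and Obp99b (1.37). Detoxification (median 0.26, adjusted p = 5.63e-06 and 0.236), odorant binding (30 of 33 up, median 0.31, adjusted p = 5.49e-07 and 0.236) and endoplasmic reticulum stress (median 0.16, adjusted p = 0.00877 and 0.31) also rose. Muscle fell, with 23 of 23 members below 0 (median -0.31, adjusted p = 1.06e-06 and 0.319), as did synaptic transmission (median -0.21, adjusted p = 1.27e-05 and 0.319). Splicing (median -0.14, adjusted p = 0.00604 and 0.319), phototransduction (-0.14, adjusted p = 0.00877 and 0.378) and Wnt (-0.14, adjusted p = 0.0364 and 0.319; nej and CkIalpha adjusted over the list alone) passed too, but their medians lie above 0 with median centring, which moved all genes by 0.15 here and ended the calls of phototransduction and Wnt (adjusted p = 0.0683 and 0.0812). Without elavII control 2 the endoplasmic reticulum stress and phototransduction calls were lost (adjusted p = 0.113 and 0.0619), and without elavII control 1 or 2x CUG line 1 that of Wnt (0.0931 and 0.0592), which was also lost without the intensity trend (0.0505).

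Across 11261 probe sets, which are not independent replicates, the log2 changes of 4x CUG and 4x AUUCU correlated at 0.678. Unchanged groups set against the same 2 controls gave 0.409 on average and 0.456 at most in 100 simulations. These drew each probe set independently, so their range leaves out probe sets that vary together. The covariance of 4x CUG and 4x AUUCU was 0.103 against 0.0358 simulated, a difference of 0.0669. In the elavII arrays alone, 12 probe sets rose in both comparisons and 3 fell in both, where independent lists would share 0.365 and 0.0824. Part of this excess may come from the shared controls. With no array shared, 4x CUG minus the mean of 4x CAG and 4x CAA correlated with 4x AUUCU minus control at 0.385. An excess was not particular to this pair: 4x AUUCU correlated with 4x CAG at 0.521 (0.412 simulated, 0.46 at most) and with 4x CAA at 0.486 (0.407, 0.455 at most). The correlation of 4x CAG with 4x CAA was 0.539 (0.499, 0.536 at most). Those of 4x CAG with 4x CUG, 0.551 (0.499, 0.553 at most), and of 4x CUG with 4x CAA, 0.53 (0.498, 0.531 at most), lay within the simulated range. The covariance differences of these other elavII pairs were smaller, 0.00855 to 0.025. In elav c155, 2x CAG correlated with 2x CUG at 0.667 (0.599 simulated, 0.637 at most). There 2x CAG with 2x CAA gave 0.497 (0.598 simulated) and 2x CUG with 2x CAA 0.398 (0.6 simulated). A value outside the simulated range therefore does not by itself show a shared response to the repeats.

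In the 4x CAG lines (n = 2) a yolk protein gene was higher. Yp3, normally transcribed in female fat body and ovary, changed by 1.37 (SE 0.23, adjusted p = 0.175 over all arrays), and rose in the elavII arrays alone (adjusted p = 0.0293). Yp1 (0.17) and Yp2 (0.83) passed in neither. CG9394 rose in that fit (0.95, adjusted p = 0.0471), and the microtubule gene Tektin-C (-2.19, adjusted p = 0.0139) and the adhesion gene fred (-1.94, adjusted p = 0.0293) fell. Over all arrays limma called 0 probe sets, with 298 at an unadjusted p under 0.05. The elavII arrays alone gave 6. Small list shifts passed camera for immunity (median 0.26, adjusted p = 0.0458), muscle (-0.11, adjusted p = 0.0355), splicing (-0.080, adjusted p = 0.0458) and the 5 tested sex markers (0.43, adjusted p = 0.0355). With an estimated correlation adjusted p = 0.831 for immunity, muscle and splicing and adjusted p = 0.25 for sex markers. The call of immunity also ended with median centring (adjusted p = 0.0611), quantile normalization (0.0758), no filter (0.157), no intensity trend (0.0639) and the replicate block (0.0577). Those of muscle, splicing and sex markers ended without the filter (0.0782, 0.0782 and 0.409) and without the trend (each 0.0639), and that of splicing with median centring (0.0933). Adjusted over the list alone Yp3 was the 1 member called in these lists. Leaving out CAG line 2 ended immunity, splicing and sex markers (adjusted p = 0.722, 0.362 and 0.168), CAG line 1 ended muscle (0.465), elavII control 2 ended immunity and muscle (both 0.339) and elavII control 1 ended splicing and sex markers (0.315 and 0.0521). Leaving out an elav c155 line ended immunity or splicing in 9 instances, with adjusted p up to 0.0587.

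In the 4x CAA lines (n = 2) Kmn1, a kinetochore gene, rose 5.76-fold (log2 change 2.53, SE 0.29, adjusted p = 0.00222), the 1 probe set called, with 422 at an unadjusted p under 0.05. It did not pass in the elavII arrays alone (adjusted p = 0.064), where CG9394 rose (1.10, adjusted p = 0.0259) and Tektin-C fell (-2.40, adjusted p = 0.00607). Without elavII control 2 the call of Kmn1 was lost (adjusted p = 0.121) and the count was 0. It was 12 without CAA line 1, 3 without CAA line 2, 4 without either CAG line and 2 without 2x CUG line 3. Proteasome genes fell, 27 of 28 below 0 (median -0.15, adjusted p = 0.0229), as did muscle (-0.14, adjusted p = 0.0153) and splicing (-0.13, adjusted p = 0.0282), and immunity rose (0.27, adjusted p = 0.0179). None had a member past the threshold adjusted over the list alone, and all lost the call with an estimated correlation (adjusted p = 0.838). Without the filter the calls of proteasome (-0.10, adjusted p = 0.468) and immunity (0.25, adjusted p = 0.0617) ended, and with median centring that of splicing (adjusted p = 0.0506). Without elavII control 2, adjusted p = 0.786 for proteasome and adjusted p = 0.24 for muscle and immunity. Without CAA line 2, adjusted p = 0.613 for proteasome and 0.577 for splicing. Without CAA line 1, adjusted p = 0.422 for immunity. Without elavII control 1, adjusted p = 0.144 for splicing.

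With elav c155 and 2 transgene copies, limma called 0 probe sets for 2x CAG, 2x CUG and 2x CAA (n = 3 each) against control (n = 2), with 755, 1028 and 309 at an unadjusted p under 0.05, and 0 in the elav c155 arrays alone. Within the immune list, adjusted over the list alone, BomS2 (1.70) rose and PGRP-SC2 (-0.66) fell in 2x CAG, PGRP-SB1 (1.2) and Drsl5 (0.76) rose and Rel (-0.47) fell in 2x CUG, and Def (1.44) rose and PGRP-SC2 (-0.84) fell in 2x CAA. Under the array set block 2x CUG had 2 calls, 1 of them CG8329, higher by 1.27 (adjusted p = 0.00107; 0.61 and 0.517 without the block). The highest count on leaving out an array was 10, for 2x CAA without control 2.

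Proteasome genes fell in 2x CAA (26 of 28 below 0, median -0.32, adjusted p = 1.86e-10; with the array set as a block -0.25, adjusted p = 6.01e-07), with adjusted p = 0.715 with an estimated correlation, and 0.745 with the block. The block also gave lower proteasome genes in 2x CAG (-0.47, adjusted p = 5.57e-08) and 2x CUG (-0.43, adjusted p = 2.98e-08), again lost with an estimated correlation (adjusted p = 0.472 and 0.75). The medians without it were -0.083 (adjusted p = 0.413) and -0.084 (adjusted p = 0.677). Cuticle genes fell in 2x CAG (36 of 48 below 0, median -0.23, adjusted p = 0.00766, and 0.693 as adjusted p with an estimated correlation). In 2x CUG detoxification (0.18, adjusted p = 0.00692) and odorant binding (0.12, adjusted p = 0.0139) rose and phototransduction fell (-0.18, adjusted p = 0.0192), each with adjusted p = 0.683 with an estimated correlation. With the block detoxification (0.044, adjusted p = 0.319) and phototransduction (0.032, adjusted p = 0.565) lost the call, and the latter turned direction. In 2x CAA splicing (0.080, adjusted p = 0.0358) and synaptic transmission (0.14, adjusted p = 0.0231) rose, and immunity (-0.23, adjusted p = 0.017), detoxification (-0.094, adjusted p = 0.017), fat body (-0.19, adjusted p = 0.0231) and glycolysis (-0.068, adjusted p = 0.0336) fell, with adjusted p = 0.715 for each with an estimated correlation. Of these, splicing, detoxification, synaptic transmission, fat body and glycolysis lost the call with the block (adjusted p = 0.153, 0.0597, 0.0817, 0.0533 and 0.0597). Without elav c155 control 1 the 6 lists had adjusted p = 0.906 and 2x CAG cuticle 0.432. Without 2x CAA line 2 the proteasome had adjusted p = 0.0854. Without 2x CAG line 3 cuticle had adjusted p = 0.0652. In 2x CUG odorant binding was lost without control 1 (adjusted p = 0.75), detoxification without control 2 (0.427) and phototransduction without control 2 (0.401), CUG line 2 (0.0841) or CUG line 3 (0.0642). In 2x CAA splicing, immunity, detoxification, fat body and glycolysis were lost without CAA line 2 (adjusted p = 0.312, 0.0607, 0.0607, 0.393 and 0.311), and these and synaptic transmission without CAA line 3 (0.062, 0.062, 0.107, 0.0589, 0.154 and 0.648). Processing choices ended further calls. In 2x CUG these were odorant binding without the filter (adjusted p = 0.0901) and phototransduction with the replicate block (0.0527). In 2x CAA the replicate block ended immunity, detoxification, synaptic transmission and fat body (each 0.0756), splicing (0.0924) and glycolysis (0.269). Quantile normalization ended fat body (0.0672) and glycolysis (0.247), and glycolysis was lost without the filter (0.0873).

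Over both experiments, CUG (5 lines) against control (4 arrays) called 1 probe set, Bbd, which rose 1.66-fold (log2 change 0.74, SE 0.10, adjusted p = 0.0258; with the array set as a block 0.66, adjusted p = 0.0302) and lay above every control of its experiment on every CUG array. Its log2 signal was 12.35, 12.78 and 12.25 in 2x CUG against 12.20 and 12.02, and 12.79 and 12.85 in 4x CUG against 11.81 and 11.58. The call was lost without elav c155 control 2 (adjusted p = 0.0969), 2x CAG line 1 (0.0574), 2x CAA line 3 (0.0522), elavII control 2 (0.192) or 4x CUG line 1 (0.0975). It also ended without the intensity trend (0.107) and with the replicate block (0.0635). With the block 26 probe sets passed, 21 up and 5 down, and included Bbd, PGRP-SB1 (1.28, adjusted p = 0.00575), a peptidoglycan recognition gene, Ance-5 (0.86, adjusted p = 0.0415), CG14629 (0.84), CG34166 (0.81), CG14495 (0.80), Mocs1 (0.52) and CG31548 (0.46), all higher, and CG11458 (-0.40), lower. Without the block 1678 had an unadjusted p under 0.05. Quantile normalization gave 41 calls, 31 up and 10 down, and median centring, which moved all genes by 0.10, gave 144, 138 up and 6 down.

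Immune genes rose on average over the 5 CUG lines (19 of 22 up, median 0.37, adjusted p = 1.14e-06, and adjusted p = 0.0535 with an estimated correlation), 8 of them adjusted over the list alone, among them PGRP-SB1 (1.30), BomS2 (0.94), Drs (0.70) and vir-1 (0.61). The median was 0.67 in 4x CUG, and the rise there exceeded that in 2x CUG by a median of 0.45 (camera adjusted p = 0.00107, and 0.438 with an estimated correlation). Every other list also lost its call with an estimated correlation, and its second adjusted p is from that test. Detoxification rose (median 0.30, adjusted p = 2.83e-06 and 0.27; 15 up and 1 down adjusted over the list alone), as did odorant binding (0.14, adjusted p = 0.000538 and 0.358; 4 up, including lush, 0.56), glia (0.091, adjusted p = 0.00929 and 0.349; alrm 1.30, wun2 0.76, mdy 0.61 and vkg 0.42) and fat body (0.16, adjusted p = 0.0107 and 0.409). Muscle (23 of 23 below 0, -0.27, adjusted p = 3.92e-05 and 0.358), phototransduction (-0.21, adjusted p = 5.69e-05 and 0.349), synaptic transmission (-0.15, adjusted p = 0.000554 and 0.409) and eye pigment (-0.14, adjusted p = 0.0362 and 0.349; Pu, -0.53, adjusted over the list alone) fell. Fitting the array set as a block ended the calls for synaptic transmission (-0.078, adjusted p = 0.102), eye pigment (-0.062, adjusted p = 0.0715) and glia (0.078, adjusted p = 0.0584), and eye pigment was also lost without the trend (0.053). Leaving out elav c155 control 2 ended fat body, glia and eye pigment (adjusted p = 0.18, 0.0696 and 0.0722), control 1 odorant binding and eye pigment (0.0801 and 0.0529), 2x CUG line 1 fat body (0.0814), and 2x CUG lines 2 and 3 eye pigment (0.0622 and 0.058).

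The count of calls for CUG moved with most arrays. It was 285 without elav c155 control 1 and 381 without 2x CUG line 1, 98 without 2x CAA line 1, 15 without 2x CAG line 2, 7 without either 4x CAG line, 5 without 4x CUG line 2, 3 without either 4x CAA line, 2 without 2x CAG line 3, 2x CAA line 2 or elavII control 1, and 0 without elav c155 control 2, 2x CAG line 1, 2x CAA line 3, elavII control 2 or 4x CUG line 1.

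Over both experiments limma called 0 probe sets for CAG and 0 for CAA against control, with 432 and 403 at an unadjusted p under 0.05. With the array set as a block CAA had 2, 1 of them the RNA-binding gene ssx (0.50, adjusted p = 0.0246). No list passed for CAG. Adjusted over the list alone BomS2 (1.2) rose in the immune list, Yp3 (0.73) in the fat body and sex marker lists, and ImpL1 (1.33) and Hr38 (0.83) in the ecdysone list. In CAA the proteasome fell (27 of 28 below 0, median -0.23, adjusted p = 5.79e-10; -0.19 and 2.53e-07 with the block), cuticle fell (-0.13, adjusted p = 0.0292), and neuropeptides (0.10, adjusted p = 0.047) and odorant binding (0.13, adjusted p = 0.047) rose. Each had adjusted p = 0.782 with an estimated correlation, odorant binding lost the call with the block (adjusted p = 0.0801), and without elav c155 control 1 adjusted p = 0.461 for cuticle, 0.155 for neuropeptides and 0.766 for odorant binding. Without the filter all 3 ended (adjusted p = 0.187, 0.124 and 0.123 for cuticle, neuropeptides and odorant binding), without the trend neuropeptides and odorant binding (both 0.0687), and cuticle with the replicate block (0.101) or quantile normalization (0.0501). Leaving out 2x CAA line 2 also ended these 3 (adjusted p = 0.177, 0.212 and 0.212), elavII control 2 ended cuticle and neuropeptides (both 0.143), elavII control 1 and 4x CAA line 2 ended odorant binding (0.663 and 0.184), and elav c155 control 2 and 4x CAA line 1 ended neuropeptides (0.0768 and 0.0762). Neuropeptides or odorant binding were also lost without 2x CUG line 2, either 4x CUG line or a 2x CAG line, with adjusted p up to 0.0728.

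Immune and detoxification genes were higher in CUG than in CAA lines over both experiments (5 lines each) by camera, and these calls were lost with an estimated correlation (adjusted p = 0.0583 and 0.0623). The Toll-induced gene BomT2 was higher by 1.22 (SE 0.22, adjusted p = 0.0303), lncRNA:CR32368 by 1.16 (SE 0.19, adjusted p = 0.0303), CG16926 by 1.14 (SE 0.23, adjusted p = 0.0482), CG4716 by 1.06, CG15293 by 1.05 and Bbd by 0.85 (SE 0.098, adjusted p = 0.00206). Def, the defensin gene, was lower (-1.14, SE 0.21, adjusted p = 0.0303), as were alpha-Catr (-0.59, adjusted p = 0.0482) and the actin nucleator gene spir (-0.38, adjusted p = 0.0303). In total 32 probe sets passed, 27 higher and 5 lower, and 1950 had an unadjusted p under 0.05. Median centring gave 127, with 123 higher and 4 lower. The array set as a block left 3, of which 1, Bbd (0.77, adjusted p = 0.0229), was among the 32. BomT2 was then 0.81 and Def -1.25 (both adjusted p = 0.0815).

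Among the lists, detoxification (58 of 75 up, median 0.32, adjusted p = 4.3e-10; 1 up over all genes, 20 up and 2 down adjusted over the list alone) and immunity (20 of 22 up, 0.34, adjusted p = 8.41e-07; 1 down over all genes, 8 up and 1 down adjusted over the list alone) were higher in CUG than CAA, with adjusted p = 0.0623 and adjusted p = 0.0583 with an estimated correlation. The other lists lost the call so too, and their second adjusted p is from that test. Neuropeptide genes were lower (27 of 32, median -0.23, adjusted p = 0.000447 and 0.337), 12 of them adjusted over the list alone, such as Crz (-0.57), Ilp5 (-0.53) and SIFa (-0.52), while Nplp4 (0.34) was higher. Phototransduction (27 of 31 lower, -0.21, adjusted p = 8.41e-06 and 0.337; 11 lower and 1 higher adjusted over the list alone, including stops, -0.57, and trpl, -0.38), synaptic transmission (41 of 45 lower, -0.17, adjusted p = 8.41e-06 and 0.381; nAChRalpha2, -0.40), eye pigment (-0.18, adjusted p = 0.0258 and 0.337; bw, -0.85) and muscle (-0.19, adjusted p = 0.00994 and 0.508) were lower, and fat body (0.22, adjusted p = 0.00289 and 0.508; 3 up adjusted over the list alone) and proteasome (26 of 28 up, 0.19, adjusted p = 0.000313 and 0.508) higher. With the array set as a block proteasome (-0.0038, adjusted p = 0.921), muscle (-0.080, adjusted p = 0.11) and eye pigment (-0.064, adjusted p = 0.0924) lost the call. Leaving out 2x CUG line 2 ended eye pigment and muscle (both adjusted p = 0.0562), 2x CUG line 3 and 2x CAA line 1 muscle (0.0995 and 0.111), and 2x CAA line 2 proteasome (0.065). For CAG against CAA limma called 0 probe sets, with 655 at an unadjusted p under 0.05. The proteasome was higher in CAG (27 of 28 up, 0.22, adjusted p = 2.72e-08), with adjusted p = 0.889 with an estimated correlation and 0.014 (adjusted p = 0.718) with the block.

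The count of 32 was 674 without 2x CAA line 1, 656 without 2x CUG line 1, 156 and 146 without elav c155 control 1 and 2, 82 without 2x CAG line 2, 20 without 2x CAG line 1, 19 without either elavII control, 18 without 4x CAA line 1, 6 without 4x CUG line 2, 3 without 2x CUG line 3 or 2x CAA line 2, 2 without 2x CUG line 2, 2x CAA line 3 or 4x CUG line 1, and 1 without 4x CAA line 2.

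Whether a repeat's effect differed between the experiments, which differ in driver and copy number together, was tested as an interaction. Limma called 0 probe sets for CAG, CUG and CAA, with 435, 622 and 315 at an unadjusted p under 0.05. Given the array set as a block it called 16 for CAG, 103 for CUG and 0 for CAA. For Gat the change in elavII minus that in elav c155 was then 2.47 for CAG and 3.00 for CUG (adjusted p = 0.0475 and 0.00617), against 0.80 and 1.33 without the block, and for alrm 1.82 for CAG (adjusted p = 0.0475), against 0.99. For CUG this difference was also positive for CG14195 (3.46, against 2.76) and the phagocytic receptor gene NimC4 (2.94, against 1.34). It was negative for CAG in fred (-2.98, against -1.62 without the block), Prosap (-1.36, against -0.38) and the neuronal RNA-binding gene fne (-1.11, against -0.59). For CUG it was negative in X11Lbeta (-3.55, against -2.96), CG34221 (-3.14, against -3.21) and CG8329 (-1.52, against -0.86).

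The log2 changes of a repeat correlated across 11261 probe sets, which are not independent replicates, between the experiments at 0.0603 for CAG, 0.261 for CUG (Spearman 0.27, 61.7% with the same sign) and 0.037 for CAA, with jackknife SEs over arrays of 0.0868, 0.202 and 0.134. The mean over matched repeats was 0.12 and over unmatched repeats 0.0369 (exact permutation p = 0.167, one-sided, the smallest that 6 assignments allow). With the array set as a block the correlation for CUG was -0.00937 and the matched mean 0.00051. 2x CUG correlated with 4x AUUCU at 0.22 without the block and 0.0312 with it.

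Akt, the kinase the series title names, passed no test in any comparison. Its log2 change was -0.24 in 2x CAG, -0.45 in 2x CUG (SE 0.30, adjusted p = 0.643), 0.12 in 2x CAA, -0.0086 in 4x CAG, -0.15 in 4x CUG (SE 0.32, adjusted p = 0.918), -0.27 in 4x CAA and -0.013 in 4x AUUCU, those of 4x CAG, 4x CUG and 4x AUUCU turning positive with median centring. Under the array set block it was 0.24 in 2x CAG and 0.03 in 2x CUG. Over both experiments CUG gave -0.30 (SE 0.22, adjusted p = 0.549). The tested Akt/Gsk3 signalling list held 21 of the 32 genes written, and sgg, the Gsk3-beta gene, was not among them. This list had a median of -0.13 in CUG over both experiments (6 up and 15 down, camera adjusted p = 0.056). Sin1, a subunit of the complex that phosphorylates Akt, fell adjusted over the list alone (-0.44, SE 0.11, adjusted p = 0.0916 over all genes), and 0 members passed over all genes. In 4x CAA the list passed without CAA line 1 (-0.12, adjusted p = 0.0334). In CUG over both experiments it passed without 2x CAG line 2 (adjusted p = 0.0456), 2x CUG line 2 (0.0484), elav c155 control 1 (0.0361), 4x CUG line 2 (0.0125) or elavII control 2 (0.0455), and with quantile normalization (0.0364). The gene trapped by the elav c155 driver, elav, changed by 0.63 in 2x CAG (SE 0.23, adjusted p = 0.723), 0.48 in 2x CUG and -0.04 in 2x CAA. With the array set as a block these changes were 0.47, 0.32 and 0.018. The log2 signal of elav in 2x CAA was 11.1 in set A and 9.9 and 10.8 in set C. In the elavII experiment elav changed by -0.23 in 4x CAG, -0.38 in 4x CUG, -0.18 in 4x CAA and -0.28 in 4x AUUCU.

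**Figure D3:**
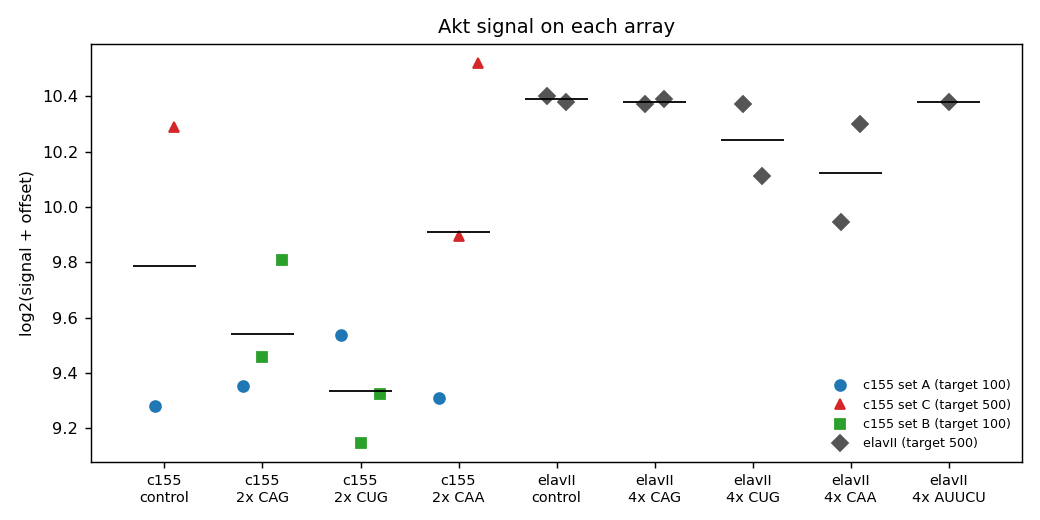
Akt log2(signal + 5.3) on each of the 20 arrays by group, with points marked by array set and a bar at each group mean. The 8 elav c155 arrays at scaling target 100 lie at 9.81 or below, and the 3 at target 500 at 9.90 or above.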

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

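The tests of head fat body, of the signal distribution, of the elavII control arrays and of the array set as a block were chosen only after the result was seen; the tests of the difference between experiments were planned. Of the 30 lists, 12 differences of a repeat's effect between experiments (elavII minus elav c155) passed camera and are given here for that reason; none passed with an estimated correlation.

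The list of repeat-RNA and alternative-splicing factors lay lower in elavII for each repeat. The median difference was -0.17 for CAG (adjusted p = 0.00176, and 0.48 with an estimated correlation), -0.11 for CUG (0.00107 and 0.477) and -0.18 for CAA (0.00131 and 0.788). The 3 repeats share the 4 control arrays. Their agreement is therefore expected in part and is not independent evidence. Humoral immunity lay higher, by 0.45 for CUG (0.00107 and 0.438) and 0.45 for CAA (0.000383 and 0.233). For CUG, muscle differed by -0.28 (0.000102 and 0.477), clock genes by -0.24 (0.0444 and 0.477), oxidative phosphorylation by -0.054 (0.0302 and 0.69), which turns positive with median centring, and fat body by 0.36 (0.0444 and 0.69). Fat body differed by 0.41 for CAA (0.0093 and 0.845), glycolysis by 0.11 for CAA (0.00878 and 0.845) and cuticle by 0.26 for CAG (0.00622 and 0.408). With the array set as a block 11 of the 12 still passed, and fat body for CUG did not (0.20, adjusted p = 0.153). Without elav c155 control 1 splicing (adjusted p = 0.287, 0.331 and 0.377 for CAG, CUG and CAA), immunity (0.111 and 0.0876 for CUG and CAA), clock (0.181), fat body (0.869 and 0.664), glycolysis (0.641) and cuticle (0.287) lost the call. Without 2x CUG line 1 muscle (0.17), clock (0.17) and oxidative phosphorylation (0.476) lost it. The CUG calls of clock and fat body were also lost without either 4x CAG line (both 0.0511) or 4x CUG line 1 (both 0.159), that of clock without elavII control 1 (0.124), and that of fat body without 2x CUG line 2 (0.1) or elavII control 2 (0.178). Oxidative phosphorylation lost it without elav c155 control 2 (0.638), 4x CUG line 2 (0.0916) or elavII control 2 (0.326). Cuticle for CAG lost it without 4x CAG line 2 (0.0729), fat body for CAA without 2x CAA line 2 (0.0826), 4x CAA line 1 (0.119) or elavII control 2 (0.0871), and glycolysis for CAA without 4x CAA line 1 (0.0798). Processing choices ended some of these calls too. For CUG, clock and fat body lost it with median centring (both 0.0618), clock without the filter (0.0573) or trend (0.0526), fat body without the trend (0.0658) or with the replicate block (0.056), and oxidative phosphorylation with median centring (0.249) and without the filter (0.13) or trend (0.0517). Glycolysis for CAA lost it with quantile normalization (0.0545).

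Immune, detoxification and fat body lists were higher and muscle, synaptic and photoreceptor lists lower in both 4x CUG and 4x AUUCU by camera, but with an estimated correlation only immunity passed (adjusted p = 0.0204 and 0.00716), and not in the elavII arrays alone (0.274 and 0.155). For the immune rise in 4x CUG, 6 of the 10 most abundant fat body transcripts (apolpp, FASN1, Desat1, Lsp2, Lsd-2 and bmm) had an upper 95% bound under the immune median. This held with the controls (bounds up to 0.50, median 0.67) and without (up to 0.34, median 0.41). It bounds a rise in head fat body only if these transcripts come mainly from fat body, which was not tested. Tsf1 (0.78), regucalcin (0.75) and Obp99b (0.72) rose above the immune median in CUG against control. More head fat body thus stays open as a source of the immune rise in 4x CUG. It also stays open for immunity in AUUCU and for the detoxification and fat body lists, where at least 5 of the 10 lay so in 2 of 10 comparisons. The CUG and AUUCU arrays have the lowest median signals of the elavII arrays (83.6, 85.4 and 84.7, controls 94.2 and 95). With quantile normalization or median centring, the largest adjusted p by camera at its preset correlation was 3.92e-07 for immunity and muscle. It was 0.00324 for detoxification, fat body and synaptic genes. This argues against the signal distribution as the whole source of these camera calls. It does not cover effects of low signal that differ between probe sets. For photoreceptor genes the largest adjusted p was 0.0683 (in AUUCU, where the median was 0.0070 with median centring and adjusted p = 0.0619 without elavII control 2), and the signal distribution stays open. Lower minus higher signal arrays within CAG and CAA correlated across probe sets at 0.152 with CUG minus control and 0.124 with AUUCU minus control. The median of this difference was 0.19 for immunity, 0.067 for fat body, 0.025 for detoxification, -0.055 for synaptic genes and -0.093 for photoreceptor genes. The signal level could therefore be a source of part of the pattern in these lists. For muscle it was 0.052, opposite to the fall in CUG and AUUCU. In 4x CUG and 4x AUUCU minus the mean of 4x CAG and 4x CAA, which uses no control, all 6 lists kept their direction. The largest adjusted p was 0.00604 by camera, but 0.218 to 0.394 with an estimated correlation. This argues against the elavII controls as the whole source only at camera's preset correlation. Both contrasts subtract the same 4x CAG and 4x CAA arrays, so their agreement is expected in part. Fat body in CUG went from 0.34 to 0.12 and immunity from 0.67 to 0.41, so the controls could be a source of part. RNA quality (actin 3'/5' ratios under both controls in CUG and AUUCU, Gapdh ratios over both in CUG), age within 0 to 3 days, line background and a response to the repeat RNAs stay open and untested.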

How the results depend on the processing

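The array set and scaling target blocks, the values as deposited, the t-test on rescaled values and the elavII arrays alone with quantile normalization or without each array were chosen only after the data were seen. Values are counts of called probe sets unless stated. The cause of a change was not tested except where said.

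Quantile normalization gave 41 for CUG versus control, 1 for CAA versus control and 57 for CUG versus CAA. Median centring gave 144, 1 and 127 for these and 69 for 4x CUG. Without the filter 4x AUUCU had 0. Without the intensity trend CUG versus control had 0, CUG versus CAA 4, 2x CUG 1, 4x CUG 2 and the CUG interaction 2. The additive model gave 11 for CUG versus control and 235 for CUG versus CAA. Fits per experiment gave 6 for 4x CAG, 432 for 4x CUG, 3 for 4x CAA and 21 for 4x AUUCU, and with quantile normalization in the elavII arrays alone 2, 424, 3 and 20.

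Counts with the array set as a block were 26 for CUG versus control, 2 for CAA versus control, 3 for CUG versus CAA, 2 for 2x CUG, 7 for 4x CAG, 450 for 4x CUG, 7 for 4x CAA, 37 for 4x AUUCU, 16 for the CAG interaction and 103 for the CUG interaction. The elavII arrays lie in no set, so their contrasts moved through the smaller residual SD, 0.18 against 0.23. 323 of the 450 for 4x CUG were also called in the elavII arrays alone. The correlations between experiments became -0.0623 for CAG and -0.00937 for CUG. With the scaling target as a block the counts were 2 for CUG versus control, 2 for CAA versus control, 2 for CUG versus CAA, 2 for 4x CAG, 183 for 4x CUG, 5 for 4x CAA, 9 for 4x AUUCU and 7 for the CUG interaction. Values as deposited gave 4 for CAG versus control, 4 for CUG versus control, 2 for CAG versus CAA, 0 for CUG versus CAA, 11 for 2x CAG, 3 for 2x CUG, 2 for 4x CAG, 1 for 4x CUG, 0 for 4x CAA, 1 for 4x AUUCU and 1 for the CUG interaction. Here arrays of a group differ by their scaling, which the setting itself leaves in.

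The methods' t-test, at their unadjusted threshold, counted 549, 503 and 314 probe sets for 2x CAG, 2x CUG and 2x CAA and 575, 1466 and 666 for 4x CAG, 4x CUG and 4x CAA on log2 values. On linear values as deposited it counted 47, 33, 0, 591, 1452 and 657, and on rescaled linear values 560, 521, 314, 591, 1452 and 657. After Benjamini-Hochberg each of these t-tests gave 0, including 4x CUG and 4x CAA.

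With the line or replicate number as a block CUG versus CAA had 3, 4x CUG 10 and 4x AUUCU 0. The numbers do not pair the arrays: residuals of arrays with the same number correlated at 0.0193 on average in elav c155 (-0.234 to 0.4) and 0.0248 in elavII (-0.0517 to 0.0811), so these counts say nothing of weaker effects.

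Leaving out each array in turn gave 0 to 2 for CAG versus control, 0 to 381 for CUG, 0 to 7 for CAA, 0 to 6 for CAG versus CAA, 1 to 674 for CUG versus CAA, 0 to 1 for 2x CAG, 0 to 4 for 2x CUG, 0 to 10 for 2x CAA, 0 to 5 for 4x CAG, 0 to 72 for 4x CUG, 0 to 12 for 4x CAA, 0 to 8 for 4x AUUCU, and 0 to 2, 0 to 4 and 0 to 4 for the CAG, CUG and CAA interactions. In the elavII arrays alone the ranges were 0 to 11, 17 to 531, 0 to 18 and 1 to 49 for 4x CAG, CUG, CAA and AUUCU. There 4x CUG had 71 without control 1, 286 without CUG line 2, 390 and 392 without CAA line 1 and 2, and 436 without AUUCU. 4x AUUCU had 35 without CUG line 1 and 14 without either CAA line, and 4x CAA had 14 without CAA line 1.

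Medians of some called lists turned direction. Without elav c155 control 1 the 2x CAA medians were -0.032 for splicing, -0.036 for synaptic transmission, 0.039 for fat body, 0.024 for glycolysis and 0.023 for detoxification. The array set block turned phototransduction in 2x CUG (0.032) and proteasome in CUG versus CAA (-0.0038). Median centring turned Wnt (0.013), splicing (0.013) and phototransduction (0.0070) in 4x AUUCU and oxidative phosphorylation in the CUG interaction (0.047). The median of the Akt/Gsk3 list, which was not called, changed sign in several comparisons and settings. Without elav c155 control 2 the 2x CAA medians were 0.221 for synaptic transmission, -0.438 for fat body and -0.181 for glycolysis. In the following counts a result is kept if its call is unchanged and, where it is called, its direction, which for lists is camera's. A result called in neither fit counts as kept whatever its sign, as for Akt and the Akt/Gsk3 list. Of 91 list results, 75 were kept with the array set block, 85 with quantile normalization and 82 with median centring. Without the filter 78 were kept, without the trend 80, without the offset 91 and with the replicate block 81. For named genes these were 62, 101, 97, 103, 90, 108 and 91. With the array set block 39 others gained the call. Signal over background limits dim probe sets: those with a mean log2 value under 5.37 were not tested in the reported counts, and the offset of 5.3 pulls low changes toward 0.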

Other observations

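The tests of the scaling target and of repeat expression for Akt and the repeat sequence test were chosen only after the result was seen, as were the genes of the next paragraph. The splits of the samples and the bounds of the array set test were set before their results, the latter when the count with the block was already known. The repeat sequence test replaced a first test, which had come out in favour of the repeat sequence (median size 0.68 in the elavII part) but was void, because its probe sets had been picked partly from the same elavII arrays.

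Some transcripts varied widely between arrays of a group. Hsp26, a small heat shock protein gene, had log2 values of 13.54 and 10.76 in the elav c155 controls and ran down to 8.83 in 2x CAG line 1, and Hsp27 and Hsp68 spread likewise, from 8.20 to 12.82 and from 8.20 to 12.66 over the elav c155 arrays. Cyp6g1, a cytochrome gene known for insecticide resistance, lay at 9.26 and 9.18 in the elav c155 controls, at 3.73 in 2x CUG line 3 and 9.55 in 2x CAA line 3, and from 10.68 to 11.69 in elavII. Tektin-C lay at 8.53, 9.59 and 9.74 in both elav c155 controls and 2x CUG line 3, at 8.97 and 8.96 in the elavII controls and at 9.52 and 9.38 in 4x CUG, and between 6.25 and 7.45 on the other arrays. Kmn1, called in 4x CAA, lay at 6.97 and 6.56 in the elavII controls, the lowest values of the 20 arrays, and at 8.93 to 9.66 in elav c155.

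Regrouping the arrays within the experiments in 60 ways tested chance for each comparison over both experiments. CUG versus CAA called 32 and 2 of 60 splits gave as many, the actual grouping included, so chance is excluded only for arrays that could be exchanged freely. The other split, with 149, exchanged CUG line 1 and CAA line 1, both of array set A. Both splits set the set B lines with 4x CUG against the set C lines with 4x CAA. Other splits of set B against set C, in which the elavII groups were mixed or turned round, gave at most 8. Mixing the elavII groups puts any 4x CUG against 4x CAA difference into the residual spread, and turning them round sets it against the elav c155 part. These splits therefore cannot show whether the array sets alone bring the count. For CAA versus control, splits of set C against set A with the elavII groups mixed gave 187, 347, 56 and 50. With the array set as a block 3 were called. Chance was not excluded for CUG versus control (1 called, 9 of 60 splits as many, highest other 578, a split that set the set B lines 2 and 3 of 2x CUG against the controls and line 1; 26 with the block). The 3 other comparisons called 0, which all 60 of 60 splits must reach, so their splits decide nothing about chance. The highest other count was 578 for CAA versus control (a split of set C against set A, which points to a structure of the samples, with 2 called with the block), 1 for CAG versus control and 20 for CAG versus CAA.

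For the 32 probe sets of CUG versus CAA, the array sets and the repeat sequence cannot be told apart. With the array set as a block the median size of their elav c155 part went from 0.67 (SD 0.34) to 0.42 (SD 0.37), a ratio of 0.622, between the bounds set for and against the array sets as the cause, and the median change of all 32 went from 0.67 (SE 0.12) to 0.56 (SE 0.12). Of the 31 that lost the call, 28 had a smaller change and 12 a larger SE, the median size of their t went from 5.53 to 4.80, and the smallest t called went from 4.99 to 6.95. Chosen independently, the 32 probe sets with the smallest p in the elavII arrays alone differed the same way in elav c155 for 28 without the block and for 20 with it (median 0.084 with the block, against 1.12 in elavII), and 20 lies between the bounds for a shared effect of the repeat sequence and against it. Across all probe sets the correlation of CUG minus CAA between experiments was 0.318 without the block and 0.0444 with it.

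Akt lay lower in 2x CAG and 2x CUG than in the elav c155 controls on average, without passing a test. The 3 arrays at scaling target 500 exceeded the 8 at target 100 by 0.83 (two-sided exact permutation p = 0.00606 over 165 assignments), every one above every other, so a difference that goes with the scaling target is a candidate source of the lower mean. Within array set A, the 2x lines differed from control by 0.07 for CAG, 0.26 for CUG and 0.03 for CAA, 1 array each. An effect of the repeats stays open, since 2x CUG minus control was 0.032 with the array set as a block and its 95% interval ran from -0.47 to 0.53. In the elavII arrays alone 4x CUG differed by -0.15 (-0.45 to 0.15).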
